A study of Mus musculus with 11 samples.

How the data were processed

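RNA was measured by bulk sequencing in 11 libraries of epidermal cells from the dorsal skin of male CD4Cre R26-tdT mice, in which cells that have expressed Cre under the CD4 promoter, and their progeny, carry the tdTomato reporter (tdT). Per the labels, the cells were released with thermolysin and sorted by FACS from a CD49f+CD34+ gate into 4 groups by Sca-1 and tdT, and each library pools 2 mice. Replicate 1 of each group came from mice of 29 weeks and the other replicates from mice of 32 weeks. The libraries were made with a TruSeq RNA v2 kit.

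The deposited files hold raw counts, 1 file per library, for 55536 Ensembl mouse genes plus 1 additional entry under a protein identifier. The authors list bcl2fastq 2.20.0.422, FastQC, STAR, featureCounts and DESeq2 1.18.1, with the genome build mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. That additional entry ran from 224 to 307 CPM in the Sca-1+ tdT+ libraries and from 4.10 to 4.89 CPM in the Sca-1+ tdT- libraries. It was read as the tdT tracer, kept out of the gene tests and reported on its own with exact Clopper-Pearson intervals at 95%. These intervals cover counting error only.

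Symbols were taken from GENCODE M21 by Ensembl identifier, which gave a symbol for 55450 genes and none for 86. Total counts ran from 17409131 to 46542177 per library. No library was a copy of another: over the 55 pairs of libraries, the smallest chi-square per degree of freedom between their counts was 51.4. Spearman correlations between replicates ran from 0.88 to 0.95 in Sca-1neg tdT+, from 0.91 to 0.99 in Sca-1neg tdT-, from 0.95 to 0.96 in Sca-1+ tdT+, and reached 0.97 in Sca-1+ tdT-.

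Counts were analysed in R 4.3.3 with edgeR 4.0.16. The low-count filter of edgeR (filterByExpr by group) left 20307 genes. Libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) was fitted to all 11 libraries with the 4 group means and no other term, which leaves 7 residual degrees of freedom. Adjusted p values come from the quasi-likelihood test of edgeR with the Benjamini-Hochberg correction over all genes tested, with a threshold of 0.05. Log2 fold changes are given with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the F statistic, since the quasi-likelihood test returns no standard error. It is rough for genes with almost no counts in a group. Gene levels are given as CPM, scaled by TMM, with the SD over the libraries of a group. Tracer CPM are shares of the total count of a library, with no TMM factor. The 6 comparisons are tdT+ against tdT- in each Sca-1 fraction, Sca-1+ against Sca-1neg in tdT- and in tdT+ cells, the tdT effect averaged over both fractions, and the difference of the tdT effect between fractions.

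Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg correction over the 36 lists in each comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Of the 669 genes on the lists and among the sort markers, 668 were found. The groups, the 6 comparisons, the 36 lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists described for each comparison were picked from the 36 after their results were seen. A list of 20 liver genes, and the alternatives that use it, were added after libraries with high Alb counts had been seen.

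Named genes are, for each comparison, up to 8 higher and 8 lower genes with the largest fold change. They were taken among those past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, without predicted genes, pseudogenes and receptor gene segments. For the difference between fractions the rule takes 5 per direction. The sort markers Cd34, Itga6 and Ly6a, the Cre promoter gene Cd4, and up to 4 members of each described list with the lowest p were named too, or the 2 most abundant members where none passed. Genes named outside this rule are marked as chosen after their values were seen.

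The alternatives were DESeq2 1.42.0 with its Wald test, DESeq2 size factors or library size alone in edgeR, no low-count filter, a minimum of 10 CPM in 2 libraries, replicate number or age as a factor, the 32-week libraries alone, only the groups being compared, a log2 fold change of at least 1, and leaving out each library in turn. Voom of limma with quality weights, a liver covariate, and a fit without the libraries with liver transcripts were added after the data were seen.

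The gene tests were run on simulated data with the same depths and dispersions, in which 200 genes changed. The quasi-likelihood test recovered from 41% to 60% of 100 genes changed 4-fold and from 1% to 4% of 100 changed 2-fold, and called from 1 to 6 unchanged genes. DESeq2 recovered from 60% to 76% and from 14% to 28%, and called from 61 to 86 unchanged genes. In separate simulations with 2 lists changed 2-fold, camera called 2 of 2 changed lists in each comparison and 1 unchanged list in 1 of them. In all these simulations genes were drawn independently of each other, so they do not measure the false calls of camera among correlated genes. Apart from the set changes, each gene had a common mean in all libraries. Structure such as the liver transcripts of some libraries was absent, so false calls of the gene tests under it were not measured either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.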

Results

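The data are gene counts from 11 libraries of sorted dorsal epidermal cells: 3 of Sca-1neg tdT+ cells, 3 of Sca-1neg tdT- cells, 3 of Sca-1+ tdT+ cells and 2 of Sca-1+ tdT- cells. CD49f (Itga6) is an integrin of basal keratinocytes, CD34 marks bulge stem cells of the mouse hair follicle, and Sca-1 (Ly6a) marks keratinocytes of the interfollicular epidermis and upper follicle. Total counts were 24764941, 18042009 and 18195195 in Sca-1neg tdT+ replicates 1 to 3, and 46542177, 39364902 and 40709279 in Sca-1neg tdT-. They were 36593970, 17409131 and 19944731 in Sca-1+ tdT+, and 30078680 and 23666873 in Sca-1+ tdT-.

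The tdT tracer stood at the labelled level in 10 of the 11 libraries. The entry was read as the tracer from its levels in labelled libraries, so this separation does not test that reading. Tracer counts were 254, 224 and 307 CPM in Sca-1+ tdT+ and 4.89 and 4.10 CPM in Sca-1+ tdT-. In the Sca-1neg fraction they were 133 and 252 CPM in tdT+ replicates 1 and 3, and 3.78, 2.54 and 2.80 CPM in tdT-. The library labelled Sca-1neg tdT+ replicate 2 held 2.05 CPM (95% Clopper-Pearson interval 1.44 to 2.83), the level of tdT- cells, and is named in this way throughout. Liver transcripts marked 3 libraries: albumin (Alb) stood at 9564 CPM in Sca-1neg tdT+ replicate 1, 4393 CPM in the library labelled Sca-1neg tdT+ replicate 2 and 6099 CPM in Sca-1neg tdT- replicate 2, against 3.04 to 37.3 CPM in the other 8 libraries. In the same 3 libraries Xist, the RNA of the inactive X chromosome, ran from 211 to 1318 CPM, against 0.400 to 1.27 CPM in the other 8. The Y-linked gene Ddx3y ran from 39.4 to 81.3 CPM in the 3 and from 125 to 154 CPM in the 8, while all mice were labelled male. A list of 20 liver genes took 1.99% to 3.61% of the counts of the 3 libraries and at most 0.0144% elsewhere.

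**Figure D1:**
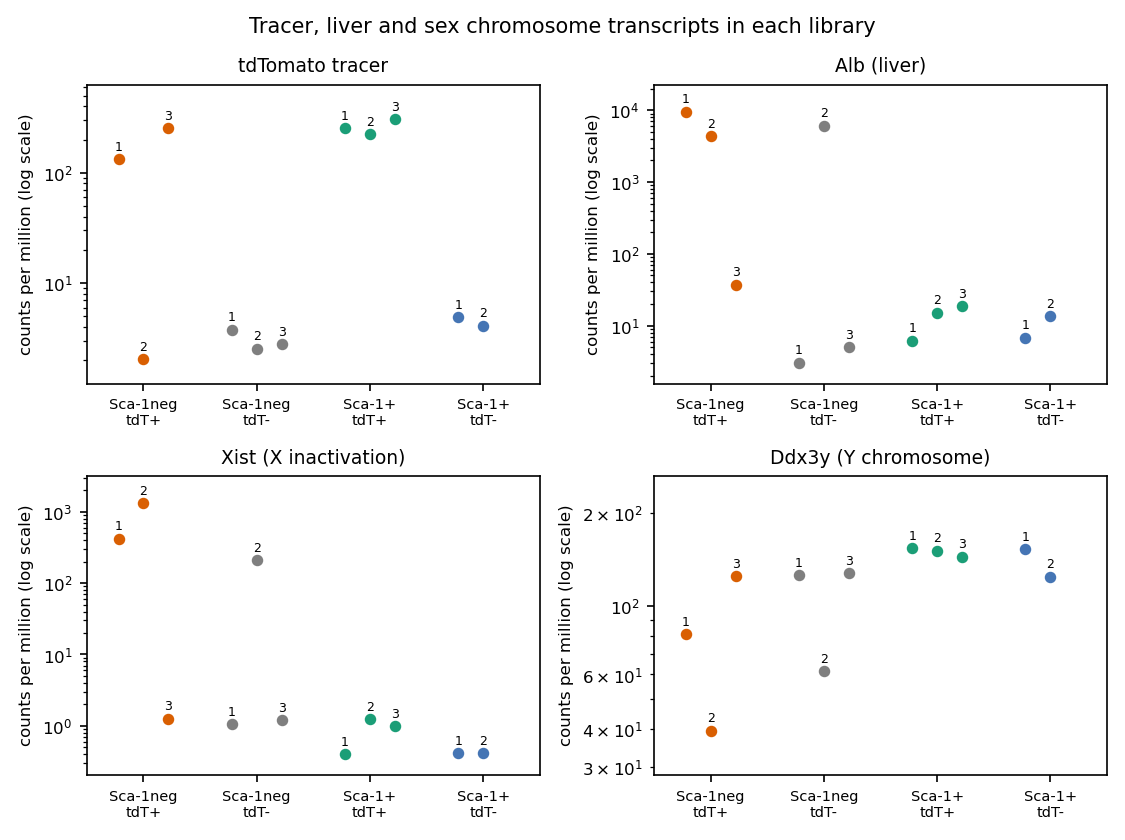
CPM (log axes) of the tdT tracer, Alb, Xist and Ddx3y in each library. Points are single libraries with their replicate number, ordered by group. The library labelled Sca-1neg tdT+ replicate 2 has the lowest tracer (2.05 CPM) and the highest Xist (1318 CPM).

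Among transcripts of the sort markers, Ly6a was 59.2 CPM in the library labelled Sca-1neg tdT+ replicate 2, at most 27.7 CPM in the other Sca-1neg libraries, and 153 to 294 CPM in Sca-1+ libraries. Itga6 was 387 to 615 CPM in Sca-1neg and 932 to 1276 CPM in Sca-1+ libraries. Cd34 was 468 to 1130 CPM in Sca-1neg libraries, 320 and 383 CPM in Sca-1+ tdT- libraries, and 22.4 to 35.7 CPM in Sca-1+ tdT+ libraries, although all libraries came from the same CD49f+CD34+ gate. Cd4, whose promoter drives the Cre, was at most 4.64 CPM in any library and passed no test, with adjusted p from 0.249 to 0.877 over the 6 comparisons.

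**Figure D2:**
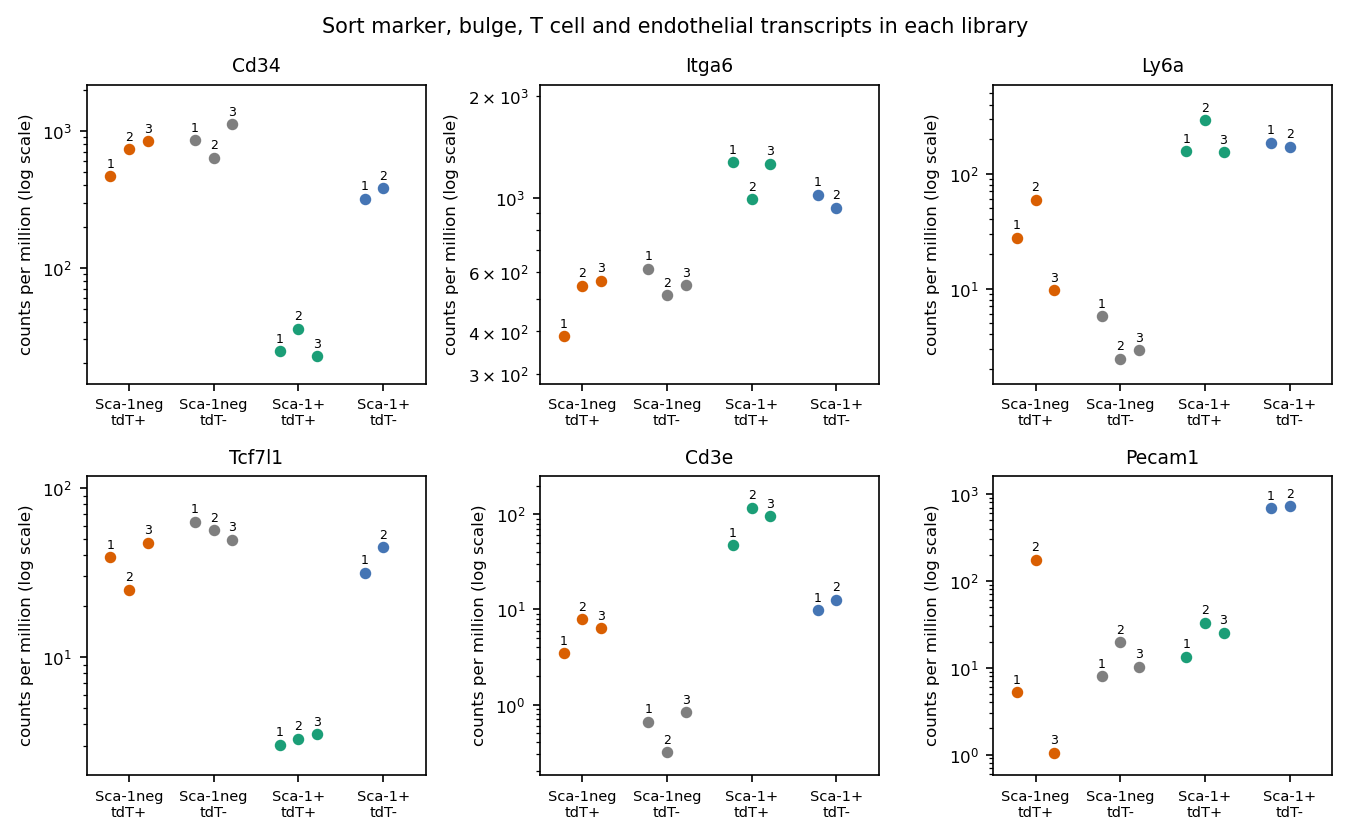
CPM (log axes) of the sort markers Cd34, Itga6 and Ly6a, the bulge gene Tcf7l1, the T cell gene Cd3e and the endothelial gene Pecam1. Points are single libraries with their replicate number, ordered by group. Cd34 is lowest in the 3 Sca-1+ tdT+ libraries (22.4 to 35.7 CPM), and Cd3e is highest there (47.1 to 117 CPM).

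The comparison of tdT+ with tdT- cells in the Sca-1neg fraction asks which transcripts differ between traced and untraced cells of this gate. It counts the library labelled Sca-1neg tdT+ replicate 2 as tdT+. Of the leukocyte lists, 2 of 24 T cell and 2 of 18 pan-leukocyte genes rose in tdT+ libraries, and none of the 25 bulge stem cell genes passed the test. No list kept its call with an estimated correlation. Cd3e (chromosome 9, 44998740 to 45009627), a signalling chain of the T cell receptor, was 5.92 ± 2.23 CPM in tdT+ and 0.603 ± 0.261 CPM in tdT- libraries (SD, n = 3 and 3; log2 fold change 3.28 ± 0.46 SE, adjusted p = 0.0404). By library, Cd3e was 3.49 and 6.39 CPM in Sca-1neg tdT+ replicates 1 and 3. It was highest, at 7.87 CPM, in the library labelled Sca-1neg tdT+ replicate 2, whose tracer was at the tdT- level. The lymphoid transcription factor Ikzf1 (chromosome 11, 11685003 to 11772926) rose by 2.94 ± 0.40, the lymphocyte adhesion regulator Cytip by 3.48 ± 0.42, Akna by 3.52 ± 0.34 and Cd7 by 2.66 ± 0.34 on the log2 scale. Ly6d rose from 66.3 ± 13.6 to 273 ± 39.4 CPM and Ahr, a ligand-activated transcription factor, from 33.5 ± 3.89 to 97.2 ± 8.49 CPM (log2 fold changes 2.04 and 1.54). Pappa, a protease that cleaves IGF-binding proteins, fell by 1.89 ± 0.27 and Ampd3, an AMP deaminase, by 1.08 ± 0.16. Of 20307 genes, 13 passed: 11 higher and 2 lower, with 1691 at an unadjusted p under 0.05. Cxcr6, Jaml and Cd163l1 were higher too (2.70, 3.19 and 3.83), and were chosen after their values were seen.

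In the lists, 2 of 24 T cell genes passed (12 adjusted over the list alone), 1 of 18 cytotoxic and epidermal gamma-delta T cell effector genes (13 adjusted over the list alone) and 2 of 18 pan-leukocyte genes (9 adjusted over the list alone), all higher. Camera adjusted p was 1.0e-15, 2.4e-16 and 8.4e-17 for these lists. They had adjusted p = 0.066, 0.066 and 0.258 with an estimated correlation. No gene of the differentiating epidermis list passed (9 of 22 higher adjusted over the list alone; median log2 fold change 1.44, camera adjusted p = 8.1e-13, adjusted p = 0.258 with an estimated correlation); Krt10 was 1410 ± 821 CPM in tdT+ and 348 ± 371 CPM in tdT-. None of 15 upper follicle genes passed either (6 higher adjusted over the list alone), with Krt79 at 794 ± 312 and 273 ± 78.8 CPM. For the upper follicle list, camera gave adjusted p = 1.8e-05, and adjusted p = 0.281 with an estimated correlation. None of 19 Langerhans cell genes passed (4 higher and 1 lower adjusted over the list alone). For the Langerhans cell list, camera gave adjusted p = 1.24e-04, and adjusted p = 0.439 with an estimated correlation, and 0.0520 without the 3 libraries with liver transcripts, where 1 tdT+ library is left. The 25 bulge genes held a median of -0.35 with 0 past the test (1 lower adjusted over the list alone), and Krt15 was 7268 ± 1688 and 10234 ± 1181 CPM. For the bulge list, camera gave adjusted p = 0.0087, and adjusted p = 0.653 with an estimated correlation. That bulge result ended without Sca-1neg tdT+ replicate 1 (camera adjusted p = 0.231), without the library labelled Sca-1neg tdT+ replicate 2 (0.172) and without Sca-1neg tdT- replicate 3 (0.0749), and it turned to higher without the 3 libraries with liver transcripts (0.671, again with 1 tdT+ library). None of 20 endothelial genes passed (1 higher and 1 lower adjusted over the list alone). The list summed to 315 CPM in Sca-1neg tdT+ replicate 1, 1050 CPM in the library labelled Sca-1neg tdT+ replicate 2 and 337 CPM in Sca-1neg tdT- replicate 2, the libraries with liver transcripts, and to 15.3, 108 and 118 CPM in the other Sca-1neg libraries. Pecam1 was 175 CPM in the library labelled Sca-1neg tdT+ replicate 2 and 5.21 and 1.05 CPM in tdT+ replicates 1 and 3. For the endothelial list, camera gave an adjusted p = 0.823 toward higher; it was 9.21e-04 toward lower without that library, and 6.52e-04 toward higher without Sca-1neg tdT+ replicate 3. Without the 3 libraries with liver transcripts it was 1.67e-10 toward lower, from 1 remaining tdT+ library.

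Other lists that camera called in this comparison held no gene past the test. None of 17 macrophage and monocyte genes passed (0 adjusted over the list alone), and 15 were positive, with Lyz2 at 68.0 ± 87.9 and 7.62 ± 11.3 CPM. For the macrophage list, camera gave adjusted p = 0.0031, and adjusted p = 0.653 with an estimated correlation. That list gave 0.281 without the library labelled Sca-1neg tdT+ replicate 2, 0.0570 without Sca-1neg tdT- replicate 3, and 0.986 toward lower without the 3 libraries with liver transcripts. None of 28 proliferation genes passed (0 adjusted over the list alone), and 27 were negative, with Mki67 at 112 ± 27.0 and 123 ± 25 CPM and Top2a at 71.9 ± 21.7 and 95.9 ± 17.3 CPM. For the proliferation list, camera gave adjusted p = 7.7e-05, and adjusted p = 0.653 with an estimated correlation. None of 7 mitochondrially encoded genes passed (2 lower adjusted over the list alone), and all 7 were negative, with mt-Co1 at 6129 ± 345 and 8261 ± 1742 CPM. For the mitochondrial list, camera gave adjusted p = 0.0032, and adjusted p = 0.512 with an estimated correlation, and 0.102 without Sca-1neg tdT- replicate 3.

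These counts rest on single libraries and on the tool. The number past the threshold was 2 without the library labelled Sca-1neg tdT+ replicate 2, 7 without Sca-1neg tdT+ replicate 3, 3 without Sca-1+ tdT+ replicate 2, 1 without Sca-1+ tdT+ replicate 3 and 0 in edgeR without Sca-1neg tdT- replicate 3 (1001 genes at an unadjusted p under 0.05), against 432 with DESeq2 and 344 with voom on all libraries. Without the 3 libraries with liver transcripts, which leaves 1 tdT+ library assumed to vary like the other groups, 38 genes passed, 22 higher and 16 lower, of which 6 were among the 13, and DESeq2 size factors gave 11 higher and 0 lower; Akna lost its call under 3 of 23 alternatives and Cd3e under 13.

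The comparison of tdT+ with tdT- cells in the Sca-1+ fraction asks the same of the Sca-1+ gate. In tdT+ libraries 9 of 24 T cell genes rose, and 9 of 25 bulge stem cell, 5 of 23 basement membrane and 1 of 20 endothelial genes fell (SD, n = 3 and 2). With an estimated correlation the T cell list kept its call (adjusted p = 0.045), and the bulge, basement membrane and endothelial lists did not (0.251, 0.260 and 0.376). Cd3d (chromosome 9, 44981786 to 44987339) rose from 3.03 ± 0.520 to 39.3 ± 29.6 CPM (log2 fold change 3.70 ± 0.63, adjusted p = 0.0108), the chemokine receptor gene Cxcr6 from 3.73 ± 0.948 to 42.8 ± 15.6 CPM (3.52 ± 0.44, adjusted p = 0.00195), and Tbx21, the transcription factor of type 1 T cells, from 1.06 ± 0.377 to 15.5 ± 7.81 CPM (3.86 ± 0.89). Tcf7l1, a Wnt repressor of follicle stem cells, fell from 38.2 ± 9.41 to 3.28 ± 0.236 CPM and Lhx2, a transcription factor of the bulge, from 200 ± 114 to 30.9 ± 10.8 CPM (log2 fold changes -3.54 ± 0.27 and -2.69 ± 0.36). Cd34 itself fell by 3.68 ± 0.32 (adjusted p = 2.96e-04), while Itga6 (0.27 ± 0.21) and Ly6a (0.17 ± 0.67, and -0.02 with voom) did not pass. The endothelial list summed to 3829 and 4311 CPM in the Sca-1+ tdT- libraries and 77.2 to 156 CPM in Sca-1+ tdT+. Bulk counts cannot tell whether Cd34, the basement membrane genes and other lower genes changed within keratinocytes or with the mix of cells.

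Of 20307 genes, 556 passed, 80 higher and 476 lower, with 2935 at an unadjusted p under 0.05. Among the higher genes with the largest change were the T cell adaptor gene Sit1 (5.39 ± 1.19), the glycosyltransferase gene B3galt5 (3.89 ± 0.80), the chemokine gene Xcl1 (3.77 ± 0.75) and Ly6g5b (3.45 ± 0.79). Nsg2 was 7.35 ± 6.64 CPM in tdT+ and 0.0158 ± 0.0224 CPM in tdT- libraries. Among the lower genes were Krt73 (chromosome 15, 101793308 to 101802346), a keratin of the inner root sheath, which fell by 5.92 ± 0.70, the homeobox genes Meox1 (-6.27 ± 1.33) and Hoxd9 (-5.57 ± 0.87), the collagen gene Col5a3 (-6.10 ± 1.20), Tmem255a (-5.76 ± 0.91), the substance P receptor gene Tacr1 (-5.63 ± 1.11), Amigo2 (-5.60 ± 1.2) and Prex2 (-5.55 ± 1.16). Of the 80 higher genes, 15 were on the leukocyte lists.

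Of 24 T cell genes, 9 rose, among them Trac (4.11 ± 0.69) and Cd3e (2.95 ± 0.51), and 15 did not pass (21 higher adjusted over the list alone). For the T cell list, camera gave adjusted p = 1.3e-22, and adjusted p = 0.045 with an estimated correlation. Of 18 cytotoxic effector genes, 5 rose (12 adjusted over the list alone), among them Cd7, the protease gene Ctsw, the integrin gene Itgae and Nkg7 (2.68, 3.23, 2.85 and 3.27). For the cytotoxic list, camera gave adjusted p = 2.6e-13, and adjusted p = 0.103 with an estimated correlation. Of 18 pan-leukocyte genes 1 rose, Ikzf1 (2.17 ± 0.45; 2 adjusted over the list alone). For the pan-leukocyte list, camera gave adjusted p = 1.78e-04, and adjusted p = 0.525 with an estimated correlation. Of 25 bulge genes, 9 fell and 0 rose (18 lower adjusted over the list alone), with Bmp6 (-2.78 ± 0.39) and Ltbp2 (-2.66 ± 0.37) beside Tcf7l1 and Lhx2. For the bulge list, camera gave adjusted p = 9.5e-12, and adjusted p = 0.251 with an estimated correlation. Of 23 basement membrane and hemidesmosome genes, 5 fell (8 adjusted over the list alone): perlecan (Hspg2, -2.76 ± 0.21), the collagen genes Col4a1, Col4a2 and Col18a1 (-3.78, -3.71 and -1.46) among them. For the basement membrane list, camera gave adjusted p = 0.0013, and adjusted p = 0.260 with an estimated correlation. Of 20 hair shaft and matrix genes 2 fell, Krt73 and Dlx3 (2 adjusted over the list alone). For the hair shaft list, camera gave adjusted p = 1.6e-06, and adjusted p = 0.260 with an estimated correlation. Of 4 mast cell genes 1 fell, Hdc, the histidine decarboxylase gene (-3.63 ± 0.68; 3 adjusted over the list alone). For the mast cell list, camera gave adjusted p = 5.8e-04, and adjusted p = 0.181 with an estimated correlation. None of 42 cytosolic ribosomal protein genes passed (18 higher adjusted over the list alone; median 0.66), with Rpl4 at 2205 ± 497 and 1467 ± 13.7 CPM. For the ribosomal list, camera gave adjusted p = 8.9e-13, and adjusted p = 0.376 with an estimated correlation.

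Camera also called the endothelial, dermal fibroblast and melanocyte lists lower, and none of these calls held with an estimated correlation. Pecam1, an adhesion molecule of endothelial cells, was 688 and 728 CPM in the Sca-1+ tdT- libraries and 13.4 to 32.9 CPM in the Sca-1+ tdT+ libraries. Of 20 endothelial genes 1 fell, Egfl7 (-5.34 ± 1.03), and 15 were lower adjusted over the list alone (median -4.94, camera adjusted p = 2.9e-11, adjusted p = 0.376 with an estimated correlation). Of 17 dermal fibroblast genes 1 fell, Sparc (-2.55 ± 0.17), and 2 were lower adjusted over the list alone. All 17 log2 fold changes were negative (median -1.46, camera adjusted p = 5.7e-06, adjusted p = 0.376 with an estimated correlation). None of 13 melanocyte genes passed (0 adjusted over the list alone), and 11 were negative, with Mitf at 10.4 ± 1.88 and 22.2 ± 0.671 CPM and Gpnmb at 42.3 ± 12.5 and 51.0 ± 13.0 CPM. For the melanocyte list, camera gave adjusted p = 0.0043, and adjusted p = 0.397 with an estimated correlation. That list gave 0.0782 without Sca-1+ tdT+ replicate 1 and 0.0803 without Sca-1+ tdT- replicate 1.

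The number past the threshold was 361 without Sca-1+ tdT+ replicate 1, 331 without Sca-1+ tdT+ replicate 3, 301 without Sca-1+ tdT- replicate 1 and 145 without Sca-1+ tdT- replicate 2, where the last 2 leave 1 tdT- library that is assumed to vary like the other groups. The higher genes among these numbered 54, 24, 17 and 1, against 80 with all libraries and 343 of 1501 with DESeq2. All that passed numbered 1286 without the 3 libraries with liver transcripts, all of which lie outside this comparison. They can enter through the shared spread, the scaling and the low-count filter, which left 21477 genes there. Fewer passed in the 32-week libraries alone, again with 1 tdT- library. Cxcr6, Tcf7l1, Lhx2, Hspg2 and Cd34 passed under all of 23 alternatives, and Tbx21, Meox1 and Prex2 lost their call under 12, 13 and 14.

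The comparison of Sca-1+ with Sca-1neg cells among untraced (tdT-) cells asks how the fractions differ without the tracer. In Sca-1+ cells 10 of 25 bulge genes and 2 of 12 Hedgehog targets fell, while 9 of 22 differentiating epidermis, 12 of 24 T cell and 8 of 25 inflammatory genes rose (SD, n = 2 and 3). No list kept its call with an estimated correlation. The bulge chemokine gene Cxcl14 fell from 3095 ± 108 to 851 ± 196 CPM (log2 fold change -1.86 ± 0.25, adjusted p = 0.00383) and the Wnt modulator gene Dkk3 from 584 ± 77.2 to 113 ± 61.1 CPM (-2.36 ± 0.36). Grhl3, a transcription factor of epidermal differentiation, rose from 6.12 ± 3.99 to 45.8 ± 11.3 CPM (2.90 ± 0.40) and Il33, an alarmin, from 13.2 ± 3.51 to 182 ± 23.6 CPM (3.79 ± 0.59). Ly6a rose by 5.59 ± 0.76 and Itga6 by 0.81 ± 0.20, and Cd34 fell by 1.32 ± 0.32 (adjusted p = 0.0367).

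Of 20307 genes, 1166 passed, 748 higher and 418 lower, with 4173 at an unadjusted p under 0.05. The median over all genes was -0.13 (log2); it was -0.05 with DESeq2 size factors, -0.26 with DESeq2 and -0.34 with no low-count filter. Among the higher genes with the largest change, Sox17 (chromosome 1, 4490931 to 4497354), a transcription factor of arterial endothelium, was 15.7 ± 1.37 CPM in Sca-1+ and 0.0333 ± 0.0411 CPM in Sca-1neg libraries, the apelin receptor gene Aplnr 34.3 ± 14.9 and 0.327 ± 0.385 CPM, and Sparcl1 111 ± 12.8 and 1.13 ± 0.0757 CPM. Rasgef1a, Gpr1, Hlx, Slfn3 and the cytokine gene Osm rose by 8.37 ± 1.62, 7.56 ± 1.74, 6.36 ± 1.03, 6.25 ± 1.4 and 6.03 ± 1.47. The lower genes included Vit (-3.01 ± 0.41), Angptl7 (-3.17 ± 0.72), the neuropeptide gene Cck (-3.23 ± 0.81), Dpysl4 (-3.26 ± 0.76), the keratin-associated Krtap17-1 (-3.08 ± 0.60), Scrg1 (-2.83 ± 0.68), the neurturin receptor gene Gfra2 (-2.77 ± 0.57) and Gprasp2 (-2.73 ± 0.53).

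Of 25 bulge genes, 10 fell (16 adjusted over the list alone), Npnt and Ltbp2 (-2.08 and -2.52) among them. For the bulge list, camera gave adjusted p = 4.7e-11, and adjusted p = 0.191 with an estimated correlation. Of 12 Hedgehog targets 2 fell, the coreceptor gene Boc (-1.53 ± 0.30) and Gli2 (-1.81 ± 0.41; 7 lower adjusted over the list alone). For the Hedgehog list, camera gave adjusted p = 8.9e-05, and adjusted p = 0.191 with an estimated correlation. Of 22 differentiating epidermis genes, 9 rose and 1 fell (15 and 1 adjusted over the list alone), with Klk7, Casp14 and Ptgs1 at 2.10, 2.46 and 3.84. For the differentiating epidermis list, camera gave adjusted p = 1.5e-10, and adjusted p = 0.191 with an estimated correlation. Of 15 upper follicle genes, 4 rose: Klk10, Gsdma, Krt79 and Cst6 (2.09, 3.06, 1.84 and 1.86; 5 adjusted over the list alone). For the upper follicle list, camera gave adjusted p = 1.56e-04, and adjusted p = 0.212 with an estimated correlation. Of 18 basal interfollicular genes, Dll1 and Tnfrsf19 rose (1.82 and 3.16; 5 higher and 2 lower adjusted over the list alone). For the basal interfollicular list, camera gave adjusted p = 0.0179, and adjusted p = 0.364 with an estimated correlation, and 0.0902 without the 3 libraries with liver transcripts.

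Of 24 T cell genes, 12 rose (14 adjusted over the list alone; camera adjusted p = 8.9e-12) and of 18 cytotoxic effector genes, 11 rose (14 adjusted over the list alone; camera adjusted p = 3.9e-13), each with an adjusted p = 0.142 with an estimated correlation. Cd3e rose from 0.603 ± 0.261 to 11.2 ± 2.00 CPM, and Cd2, Tcrg-C1, Itgae and Klrk1 rose by 4.44, 4.26, 3.89 and 4.24. Of 18 pan-leukocyte genes, 6 rose, with Cytip, Ikzf1, Arhgdib and Coro1a (4.60, 3.64, 2.41 and 2.86; 12 adjusted over the list alone). For the pan-leukocyte list, camera gave adjusted p = 5.9e-13, and adjusted p = 0.191 with an estimated correlation. Of 17 macrophage and monocyte genes 1 rose, Itgam (5.77 ± 1.24; 3 adjusted over the list alone), and all 17 were positive. For the macrophage list, camera gave adjusted p = 1.5e-05, and adjusted p = 0.432 with an estimated correlation. Of 4 mast cell genes 1 rose, Hdc (4.79 ± 0.71; 3 adjusted over the list alone). For the mast cell list, camera gave adjusted p = 0.0063, and adjusted p = 0.191 with an estimated correlation. Of 19 Langerhans cell genes, 6 rose, with Cd83 (4.52 ± 0.77), H2-Aa (3.80 ± 0.67) and H2-Eb1 (4.0 ± 0.74), and Id2 fell (-1.96 ± 0.33; 10 and 1 adjusted over the list alone). For the Langerhans cell list, camera gave adjusted p = 4.2e-07, and adjusted p = 0.191 with an estimated correlation. Of 14 class I antigen presentation genes, 5 rose, among them the proteasome genes Psmb8 and Psmb9 (0.99 and 0.93), Nlrc5 (1.36) and H2-Q7 (1.0; 12 adjusted over the list alone). For the class I list, camera gave adjusted p = 2.1e-08, and adjusted p = 0.191 with an estimated correlation. Of 25 inflammatory cytokine and chemokine genes, 8 rose, with Tnf (3.83 ± 0.57), Tnfaip3 (2.43 ± 0.40) and Csf1 (1.44 ± 0.27) beside Il33 (14 higher and 1 lower adjusted over the list alone). For the inflammatory list, camera gave adjusted p = 2.0e-10, and adjusted p = 0.191 with an estimated correlation. None of 26 interferon-stimulated genes passed (0 adjusted over the list alone; median 1.44). For the interferon list, camera gave adjusted p = 2.8e-06, and adjusted p = 0.424 with an estimated correlation. Of 7 mitochondrially encoded genes 2 fell, mt-Cytb (-0.85 ± 0.21) and mt-Nd4 (-0.74 ± 0.19; 4 adjusted over the list alone). For the mitochondrial list, camera gave adjusted p = 0.0081, and adjusted p = 0.485 with an estimated correlation, and 0.0525 without Sca-1+ tdT- replicate 2. Of 20 endothelial genes 2 rose, Sox17 and Ly6c1 (5.51 ± 1.29), with a list median of 4.86 (13 higher adjusted over the list alone). For the endothelial list, camera gave adjusted p = 3.7e-08, and adjusted p = 0.371 with an estimated correlation. Of 17 dermal fibroblast genes 1 rose, Pi16 (4.57 ± 1.11; 2 adjusted over the list alone). For the dermal fibroblast list, camera gave adjusted p = 0.0157, and adjusted p = 0.516 with an estimated correlation. That list gave 0.0613 without Sca-1neg tdT- replicate 1 and 0.156 without Sca-1+ tdT- replicate 2. None of 28 proliferation genes passed (0 adjusted over the list alone; median 0.61), with Mki67 at 231 ± 36.4 and 123 ± 25 CPM and Top2a at 166 ± 35.8 and 95.9 ± 17.3 CPM. For the proliferation list, camera gave adjusted p = 2.2e-05, and adjusted p = 0.501 with an estimated correlation.

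The number past the threshold was 601 without Sca-1neg tdT- replicate 1, 301 without Sca-1neg tdT- replicate 3, 116 without Sca-1+ tdT- replicate 1 and 493 without Sca-1+ tdT- replicate 2. It was 2073 without the 3 libraries with liver transcripts and 2980 with DESeq2, and 9 in the 32-week libraries alone, which leave 1 Sca-1+ tdT- library assumed to vary like the other groups; Grhl3, Cd7 and Itgae passed under all of 23 alternatives, while Cck and mt-Cytb lost their call under 14 each.

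The comparison of Sca-1+ with Sca-1neg cells among traced (tdT+) cells asks the same of cells with the tracer. It counts the library labelled Sca-1neg tdT+ replicate 2 as tdT+ (SD, n = 3 and 3). In Sca-1+ tdT+ cells 23 of 25 bulge genes fell, and 19 of 24 T cell, 13 of 18 cytotoxic and 9 of 28 proliferation genes rose. No list kept its call with an estimated correlation. Tcf7l1 fell from 37.2 ± 11.3 to 3.28 ± 0.236 CPM (log2 fold change -3.5 ± 0.26, adjusted p = 6.02e-05), the matrix gene Ltbp2 from 253 ± 93.8 to 7.41 ± 2.41 CPM (-5.08 ± 0.39) and Cd34 by 4.64 ± 0.32 (adjusted p = 5.43e-05). Krt14, a keratin of basal cells, rose from 3146 ± 548 to 11765 ± 2688 CPM (1.90 ± 0.22), Cd3e from 5.92 ± 2.23 to 86.7 ± 36.0 CPM (3.87 ± 0.46), Itga6 by 1.23 ± 0.18 and Ly6a by 2.65 ± 0.64.

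Of 20307 genes, 2572 passed, 1206 higher and 1366 lower, with 6064 at an unadjusted p under 0.05. The higher genes included those for CD40 ligand (Cd40lg, 5.48 ± 2.72 against 0.0357 ± 0.0618 CPM), the chemokine receptor CCR8 (Ccr8, 5.14 ± 1.49 against 0.0330 ± 0.0288 CPM) and interferon gamma (Ifng, 9.77 ± 5.68 against 0.235 ± 0.268 CPM), with B3galt5, Sit1, Rnase2b and Ptpn5 (5.64 ± 0.74, 5.30 ± 1.0, 5.23 ± 1.52 and 5.03 ± 0.59). Olfr523 had 0 counts in all Sca-1neg tdT+ libraries and was at least 137-fold higher in Sca-1+ tdT+, taking 3 counts over the group as the limit. The lower genes Thrsp, Iyd, Cmbl, C1rl and Shroom1 moved with the liver transcripts, as seen after their values were examined: C1rl was 34.9, 16.1 and 18.1 CPM in the 3 libraries with liver transcripts and at most 2.59 CPM in the other Sca-1neg libraries, and Cmbl 20.9, 5.78 and 9.57 CPM against at most 1.07 CPM. Kcnd3, Rab17 and Enho were the other lower genes with the largest change, with adjusted p = 0.00106, 0.00112 and 0.00112.

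Of 25 bulge genes, 23 fell (23 adjusted over the list alone), with Cxcl14 and Dkk3 (-2.46 and -3.73). For the bulge list, camera gave adjusted p = 2.0e-16, and adjusted p = 0.152 with an estimated correlation. Of 12 Hedgehog targets, 7 fell, with Gli1 and Gli2, the transcription factors of the pathway (-3.47 and -2.66), Boc (-1.81) and Hhip (-6.56; 7 adjusted over the list alone). For the Hedgehog list, camera gave adjusted p = 9.7e-04, and adjusted p = 0.542 with an estimated correlation. Of 22 BMP and TGF-beta response genes, 7 fell: Ccn2, Smad6, Id2 and Id4 (-3.35, -2.68, -2.23 and -2.74) among them (2 higher and 10 lower adjusted over the list alone). For the BMP and TGF-beta list, camera gave adjusted p = 0.0137, and adjusted p = 0.567 with an estimated correlation, and 0.0975 without Sca-1neg tdT+ replicate 3. Of 13 melanocyte genes 2 fell, Mitf (-2.77 ± 0.37) and Kit (-1.70 ± 0.40; 1 higher and 6 lower adjusted over the list alone). For the melanocyte list, camera gave adjusted p = 0.0055, and adjusted p = 0.567 with an estimated correlation, and 0.111 without the 3 libraries with liver transcripts. Of 18 basal interfollicular genes, 5 rose, among them Krt14, Krt5 (0.68 ± 0.18), Dll1 (1.32 ± 0.26) and Tnfrsf19 (2.30 ± 0.54; 7 adjusted over the list alone). For the basal interfollicular list, camera gave adjusted p = 0.0021, and adjusted p = 0.485 with an estimated correlation, and 0.132 without the 3 libraries with liver transcripts. Of 22 differentiating epidermis genes, 4 rose, with Casp14, Grhl3 and Mt4 (1.67, 1.55 and 1.53), and Calml3 fell (-2.85 ± 0.36; 8 and 1 adjusted over the list alone). For the differentiating epidermis list, camera gave adjusted p = 0.0146, and adjusted p = 0.595 with an estimated correlation, and 0.0583 without Sca-1neg tdT+ replicate 3 and 0.0609 without Sca-1+ tdT+ replicate 3.

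Of 24 T cell genes, 19 rose (21 adjusted over the list alone), and of 18 cytotoxic effector genes, 13 rose (16 adjusted over the list alone). For the T cell list, camera gave adjusted p = 8.3e-18, and adjusted p = 0.088 with an estimated correlation. For the cytotoxic list, camera gave adjusted p = 2.5e-13, and adjusted p = 0.106 with an estimated correlation. Examples were Thy1 (3.36), and Cd7, Itgae, Nkg7 and Ctsw (3.56, 3.99, 4.52 and 3.81); Bcl11b, which keratinocytes express too, rose by 1.43 ± 0.15. Of 18 pan-leukocyte genes, 4 rose: Arhgdib, Ikzf1, Cytip and Coro1a (2.22, 2.87, 2.31 and 2.10; 6 adjusted over the list alone). For the pan-leukocyte list, camera gave adjusted p = 7.0e-07, and adjusted p = 0.567 with an estimated correlation. Of 28 proliferation genes, 9 rose, among them Mcm6 (0.61 ± 0.13), Cenpf (1.08 ± 0.25), Foxm1 (1.03 ± 0.25) and Cdc20 (1.10 ± 0.27; 24 adjusted over the list alone). For the proliferation list, camera gave adjusted p = 1.2e-08, and adjusted p = 0.567 with an estimated correlation. Of 14 class I antigen presentation genes, 6 rose, with Psmb8, Psmb9, Nlrc5 and Tap1 (0.88, 0.84, 1.0 and 0.81; 8 adjusted over the list alone). For the class I list, camera gave adjusted p = 0.00115, and adjusted p = 0.567 with an estimated correlation, and 0.0786 without the 3 libraries with liver transcripts. Of 26 interferon-stimulated genes 3 rose, among them Ifi27 and Oas1a (0.66 and 2.66; 3 adjusted over the list alone). For the interferon list, camera gave adjusted p = 0.0023, and adjusted p = 0.595 with an estimated correlation, and 0.134 without Sca-1neg tdT+ replicate 3. Of 7 mitochondrially encoded genes 2 fell, mt-Nd4 and mt-Cytb (-0.64 and -0.64; 3 adjusted over the list alone). For the mitochondrial list, camera gave adjusted p = 0.0369, and adjusted p = 0.595 with an estimated correlation. That list's camera adjusted p was 0.0710 without the library labelled Sca-1neg tdT+ replicate 2, 0.0884 without Sca-1neg tdT+ replicate 3, 0.0934 and 0.0607 without Sca-1+ tdT+ replicates 1 and 2, and 0.0808 without the 3 libraries with liver transcripts. None of 20 endothelial genes passed (0 adjusted over the list alone; median -1.98, camera adjusted p = 0.760 toward lower); the list gave 0.0251 toward higher without the library labelled Sca-1neg tdT+ replicate 2, 0.00632 toward lower without Sca-1neg tdT+ replicate 3, 0.985 toward higher without Sca-1+ tdT+ replicate 1 and 2.35e-07 toward higher without the 3 libraries with liver transcripts.

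The number past the threshold was 1591 without Sca-1neg tdT+ replicate 1 and 345 in the 32-week libraries alone. Without the 3 libraries with liver transcripts, which leaves 1 Sca-1neg tdT+ library, 2221 genes passed, of which 1419 were among the 2572, all with the same sign; Tcf7l1, Ltbp2, Cd34, Cd3e and Cd7 passed under all of 23 alternatives, and Thrsp and Cmbl lost their call under 12 each.

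**Figure D3:**
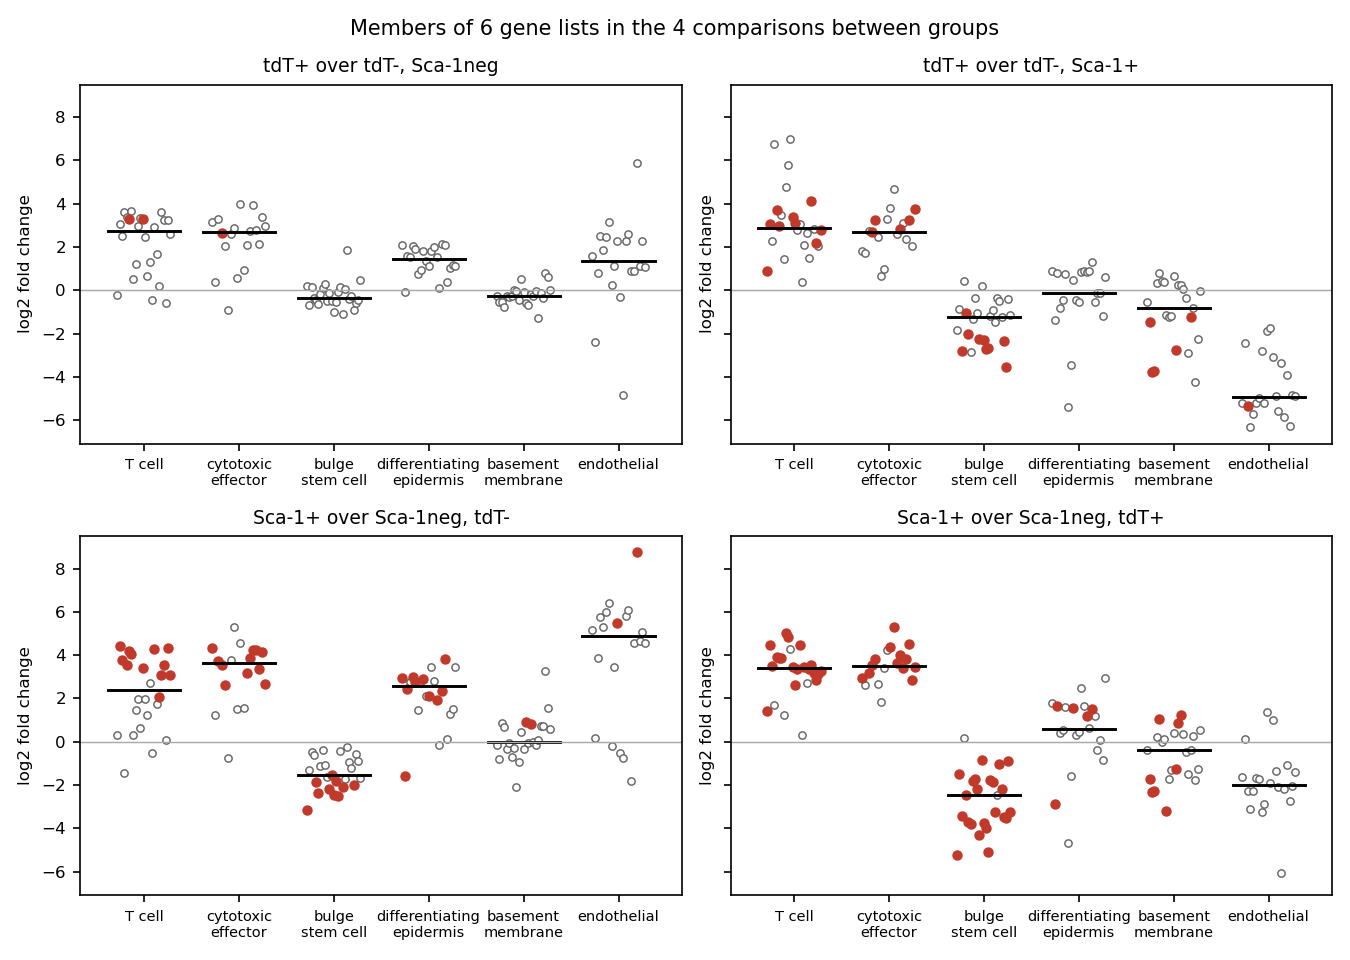
Log2 fold changes of the members of 6 gene lists in the 4 comparisons between groups. Filled points passed the test, open points did not, and bars are list medians. The T cell medians are 2.75, 2.89, 2.40 and 3.42, and the endothelial medians 1.35, -4.94, 4.86 and -1.98, in the order of the panels.

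The tdT effect averaged over both fractions asks which genes differ between traced and untraced cells in the mean of the Sca-1 gates. Such a mean can be carried by a single fraction. No bulge gene passed in Sca-1neg, and the tdT effects on Cd34 and Tcf7l1 differed between fractions, as given below. It counts the library labelled Sca-1neg tdT+ replicate 2 as tdT+ (n = 6 and 5 libraries). In tdT+ libraries 12 of 24 T cell and 10 of 18 cytotoxic genes rose, and 9 of 25 bulge, 4 of 23 basement membrane, 2 of 17 dermal fibroblast and 1 of 20 endothelial genes fell. With an estimated correlation the T cell and cytotoxic lists kept their calls (adjusted p = 0.0225 and 0.030), and the other 4 did not (0.259 to 0.436). The endothelial transcripts of the Sca-1+ tdT- libraries enter this mean too, so lower genes may reflect the mix of cells. The receptor chains Cd3d (log2 fold change 3.53 ± 0.43, adjusted p = 0.00248), Cd3g (3.57 ± 0.67), Cd3e (3.12 ± 0.35) and Trac (3.86 ± 0.46), the killer cell receptor gene Klrd1 (3.5 ± 0.61), Xcl1 (3.38 ± 0.50), the adaptor gene Hcst (3.25 ± 0.63) and Ms4a4b (3.11 ± 0.67) rose. Tnc (tenascin C, -2.56 ± 0.40), Bgn (biglycan, -2.83 ± 0.31), the endothelial list gene Mmrn1 (-3.97 ± 0.83), Scrg1 (-3.21 ± 0.46), Rasl12 (-2.91 ± 0.63), Dpysl4 (-2.40 ± 0.49), Pkhd1l1 (-2.36 ± 0.38) and Gfra2 (-2.32 ± 0.36) fell. Cd34 fell by 2.02 ± 0.21, and Itga6 (0.05 ± 0.14) and Ly6a (1.64 ± 0.48, adjusted p = 0.162) did not pass.

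Of 20307 genes, 457 passed, 135 higher and 322 lower, with 2632 at an unadjusted p under 0.05. DESeq2 gave 1258, 502 higher and 756 lower. Of 24 T cell genes, 12 rose (22 adjusted over the list alone), and of 18 cytotoxic effector genes, 10 rose (13 adjusted over the list alone), with Cd7, Itgae and Ctsw at 2.67, 2.80 and 2.64. For the T cell list, camera gave adjusted p = 1.4e-28, and adjusted p = 0.0225 with an estimated correlation. For the cytotoxic list, camera gave adjusted p = 5.9e-21, and adjusted p = 0.030 with an estimated correlation. Of 18 pan-leukocyte genes, 5 rose, with Ikzf1, Cytip, Coro1a and Cd52 (2.56, 2.34, 1.71 and 2.62; 10 adjusted over the list alone). For the pan-leukocyte list, camera gave adjusted p = 8.1e-14, and adjusted p = 0.261 with an estimated correlation. Of 25 bulge genes, 9 fell, with Tcf7l1, Tbx1, Lhx2 and Dkk3 (-2.07, -1.62, -1.62 and -1.33; 14 adjusted over the list alone). For the bulge list, camera gave adjusted p = 1.4e-11, and adjusted p = 0.259 with an estimated correlation. Of 23 basement membrane and hemidesmosome genes, 4 fell: Hspg2, Col4a2, Col4a1 and Col18a1 (-1.68, -2.23, -2.17 and -1.0; 8 adjusted over the list alone). For the basement membrane list, camera gave adjusted p = 8.0e-05, and adjusted p = 0.259 with an estimated correlation. Of 20 endothelial genes 1 fell, Mmrn1 (3 lower adjusted over the list alone), and 18 were negative (median -1.66). In the Sca-1neg tdT- libraries without liver transcripts, Mmrn1 was the only gene of that list at a mean of 10 CPM or more. Over all Sca-1neg tdT- libraries it was 25.2 ± 2.44 CPM. For the endothelial list, camera gave adjusted p = 3.9e-07, and adjusted p = 0.436 with an estimated correlation. Of 17 dermal fibroblast genes 2 fell, Sparc and Mmp2 (-1.64 and -1.01; 2 adjusted over the list alone), and 16 were negative. For the dermal fibroblast list, camera gave adjusted p = 3.26e-04, and adjusted p = 0.436 with an estimated correlation.

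The number past the threshold was 291 without Sca-1neg tdT- replicate 1, 253 without Sca-1neg tdT- replicate 3 and 138 without Sca-1+ tdT- replicate 2. It was 709 without the 3 libraries with liver transcripts and 41 in the 32-week libraries alone, which leave 1 Sca-1+ tdT- library; Cd3e, Cd3d, Trac, Cd7, Itgae, Tcf7l1, Lhx2, Tbx1, Hspg2, Tnc and Bgn passed under all of 22 alternatives.

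The difference of the tdT effect between fractions asks whether tdT+ and tdT- cells differ in another way in Sca-1+ than in Sca-1neg cells. It counts the library labelled Sca-1neg tdT+ replicate 2 as tdT+. Between fractions 1 of 20 endothelial and 2 of 25 bulge genes differed toward lower in Sca-1+. The endothelial medians were -4.94 in Sca-1+ and 1.35 in Sca-1neg, where the list summed to 1050 CPM in the library labelled Sca-1neg tdT+ replicate 2 and to 315 and 15.3 CPM in tdT+ replicates 1 and 3. The difference was -9.81 ± 1.52 (log2) for Sox17, -7.32 ± 1.15 for Thsd7a, -7.03 ± 1.24 for the glutamate receptor gene Gria3, -6.53 ± 1.11 for Hspa12b and -6.36 ± 1.14 for Tmem255a, and -2.94 ± 0.35 for Tcf7l1 (adjusted p = 0.00559). It was -3.31 ± 0.41 for Cd34 (adjusted p = 0.00695). Agap2, Adamtsl5 and Lancl1 went the other way (2.56 ± 0.47, 1.48 ± 0.24 and 1.15 ± 0.20).

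Of 20307 genes, 98 passed, 3 higher and 95 lower, with 2476 at an unadjusted p under 0.05. Voom gave 680, 90 higher and 590 lower. Of 25 bulge genes 2 were lower, Tcf7l1 and Bmp6 (-2.96 ± 0.52; 8 adjusted over the list alone, camera adjusted p = 5.7e-06), of 22 differentiating epidermis genes 1, Klk7 (-1.64 ± 0.30; 1 adjusted over the list alone, 1.87e-05 and 0.0828 without the 3 libraries with liver transcripts), and of 20 endothelial genes 1, Sox17 (14 adjusted over the list alone, 1.3e-07). None of 24 T cell genes passed (2 higher adjusted over the list alone; median 0.73, camera adjusted p = 9.52e-04), none of 15 upper follicle genes (5 lower adjusted over the list alone; 0.0015, and 0.0869 without Sca-1neg tdT+ replicate 3), none of 19 Langerhans cell genes (5 lower adjusted over the list alone; 5.7e-06) and none of 42 cytosolic ribosomal protein genes (7 higher adjusted over the list alone; 3.3e-12). Each of these 7 lists had an adjusted p = 0.481 with an estimated correlation. The number past the threshold was 347 without Sca-1neg tdT+ replicate 3, 43 and 45 without Sca-1neg tdT- replicates 1 and 3, 64 without Sca-1+ tdT+ replicate 1, and 54 and 26 without Sca-1+ tdT- replicates 1 and 2. It was 220 without the 3 libraries with liver transcripts and 0 in edgeR in the 32-week libraries alone, with 1 Sca-1+ tdT- library (1119 genes at an unadjusted p under 0.05), against 891 with DESeq2 and 680 with voom on all libraries.

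Across the 20307 genes, which are not independent replicates, the log2 fold changes of the tdT effect in the 2 fractions had a Pearson correlation of 0.0044 and a Spearman correlation of 0.037. Calls overlapped nonetheless: 7 genes were higher in both fractions (0.043 expected by chance), 1 was lower in both (0.047 expected) and 0 were opposite, while all 13 genes called in Sca-1neg had the same sign in Sca-1+ and 377 of the 556 called in Sca-1+ had the same sign in Sca-1neg. The Pearson correlation was 0.076 without the library labelled Sca-1neg tdT+ replicate 2 and -0.042 without Sca-1neg tdT+ replicate 3. Over genes with at least 10 CPM in 2 libraries it was -0.111, while the Spearman correlation was 0.075. The Sca-1 effects in tdT- and tdT+ cells had a Pearson correlation of 0.53 and a Spearman correlation of 0.46, with 386 genes higher in both (44.4 expected), 306 lower in both (28.1 expected) and 30 opposite. That Pearson correlation was 0.128 without Sca-1neg tdT- replicate 2, 0.346 and 0.396 without Sca-1+ tdT- replicates 1 and 2, and 0.332 without the 3 libraries with liver transcripts.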

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

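The tests of the tracer in the library labelled Sca-1neg tdT+ replicate 2 were all chosen after its value was seen, while the difference of the tdT effect between fractions was planned before the data were examined. That difference passed the test for 98 genes and counts this library as tdT+. It was 2.56 for Agap2, 1.48 for Adamtsl5 and 1.15 for Lancl1, and -9.81 for Sox17, -7.32 for Thsd7a, -7.03 for Gria3, -6.53 for Hspa12b and -6.36 for Tmem255a (log2). The median difference was 0.73 for the T cell list, -1.36 for bulge genes, -1.11 for upper follicle genes, -1.22 for differentiating epidermis genes, -6.77 for endothelial genes, -2.33 for Langerhans cell genes and 0.82 for cytosolic ribosomal protein genes. Each of these 7 lists had an adjusted p = 0.481 with an estimated correlation.

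The tracer has no gene symbol and is outside the gene tests. It stood at 133 and 252 CPM in Sca-1neg tdT+ replicates 1 and 3, and at 254, 224 and 307 CPM in the Sca-1+ tdT+ libraries. In the library labelled Sca-1neg tdT+ replicate 2 it stood at 2.05 CPM, with an upper 95% Clopper-Pearson limit of 2.83 CPM. A swap with a Sca-1neg tdT- library is excluded, since the highest tracer among those was 3.78 CPM. Dilution of tdT+ cells of male mice by RNA without Y transcripts is excluded too: the Y genes stood at 0.279 to 0.289 of their mean in the other 8 libraries, which would leave 37.2 CPM of tracer. An unmixed Sca-1neg tdT- library under a wrong label would hold few T cell transcripts. The cytotoxic effector list summed to 74.9 CPM in the library in question, against 6.71 to 18.9 CPM in the Sca-1neg tdT- libraries. Its low Y gene shares point to other RNA in it, which may carry T cell transcripts. A wrong label together with such RNA therefore stays open. A mixture of Sca-1+ tdT- with Sca-1neg tdT- cells would need differing shares of the former. These were 0.222 by the endothelial list, 0.316 by Ly6a and 0.582 by the cytotoxic effector list. Cells or mice outside those the labels describe may be a source, which was not tested.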

How the results depend on the processing

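The voom fits, the liver covariate, the fits without the 3 libraries with liver transcripts, and the lists and correlations with libraries left out were chosen after the data were seen. No named gene that passed the test changed direction in these alternatives. Of 326 results of named genes, 78 kept their outcome in the 32-week libraries alone, 268 without the 3 libraries with liver transcripts, 286 with replicate number as a factor, 295 with voom and 320 of 323 tested with DESeq2. Of 68 list results, 5 kept their outcome with an estimated correlation, 35 with fry, 57 without the 3 libraries with liver transcripts and 68 with replicate number as a factor.

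The labels do not say what a replicate number shares. After removal of group means, libraries with the same number correlated from -0.42 to 0.59, above 0.10 in 7 of 15 pairs, against 2 of 30 pairs with different numbers. Of 11 libraries, 7 correlated best with their own number, a hint from the data and not the design. The numbers were not taken as pairs, since not every pair was above 0.10. Liver transcripts may have entered these correlations. Sca-1neg tdT+ replicate 1 correlated at -0.42 with Sca-1neg tdT- replicate 1, and at 0.51 with Sca-1neg tdT- replicate 2, which holds them too. A pair without such libraries, Sca-1neg tdT- and Sca-1+ tdT+ replicate 3, was also below 0.10 (-0.045). With replicate block, 15, 502, 1027, 2571, 490 and 123 genes passed in the 6 comparisons, of which 8, 424, 893, 2264, 393 and 84 were among those without it.

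For tdT+ against tdT- in Sca-1neg, 13 genes passed, against 432 with DESeq2, 344 with voom, 81 with no low-count filter, 8 with age as a factor, 24 with the liver covariate and 38 without the 3 libraries with liver transcripts. The edgeR test gave 0 in the 32-week libraries alone (747 at an unadjusted p under 0.05) and 0 with these groups alone (1441). Leaving out single libraries gave 0 to 14. In Sca-1+, 556 passed, against 1501 with DESeq2, 1172 with voom, 64 in the 32-week libraries alone, 1286 without the 3 libraries, 996 with the liver covariate and 957 with these groups alone (145 to 791 without single libraries).

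For Sca-1+ against Sca-1neg in tdT-, 1166 passed, against 2980 with DESeq2, 4232 with voom, 9 in the 32-week libraries alone, 2073 without the 3 libraries, 2293 with the liver covariate and 2003 with these groups alone (116 to 1665 without single libraries). In tdT+, 2572 passed, against 4773 with DESeq2, 345 in the 32-week libraries alone and 1584 with these groups alone (1591 to 3040 without single libraries). The averaged tdT effect gave 457 genes, 1258 with DESeq2, 940 with voom, 41 in the 32-week libraries alone and 709 without the 3 libraries (138 to 477 without single libraries). Its difference between fractions gave 98, 891 with DESeq2, 680 with voom, 156 with DESeq2 size factors, 234 with no filter, 172 at a minimum of 10 CPM, 220 without the 3 libraries and 202 with the liver covariate (26 to 347 without single libraries). In the 32-week libraries alone edgeR gave 0 (1119 at an unadjusted p under 0.05).

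The Pearson correlation of the tdT effects was 0.0044, 0.118 with replicate number as a factor and -0.111 at a minimum of 10 CPM (Spearman 0.075). It was 0.0955 without the 3 libraries and -0.042 to 0.0758 without single libraries. That of the Sca-1 effects was 0.528, 0.707 at a minimum of 10 CPM, 0.332 without the 3 libraries and 0.128 to 0.553 without single libraries.

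Some values changed sign. Those of genes named here passed no test: Itga6 was 0.061 in the 32-week libraries (tdT effect in Sca-1neg, -0.16), Cd4 -0.16 with voom (1.02) and Ly6a -0.022 with voom (tdT effect in Sca-1+, 0.17; -0.27 to 0.33 without single libraries). Cd4 between Sca-1 fractions in tdT- was 0.46, and -0.043 with replicate number as a factor, -0.056 with age, -1.89 in the 32-week libraries and -1.62 to 1.31 without single libraries. Itga6 in the averaged effect was -0.0054 to 0.13 without single libraries. Camera called the bulge list in Sca-1neg lower with all libraries (adjusted p = 0.0087) and the macrophage list higher (0.0031), and both turned without the 3 libraries, which leaves 1 tdT+ library, to 0.671 toward higher and 0.986 toward lower. The endothelial list in Sca-1neg, not called with all libraries, turned to lower with fry (0.976), DESeq2 size factors (0.872) and without the 3 libraries (1.669e-10), and ran from 6.519e-04 to 0.9999 without single libraries. Between Sca-1 fractions in tdT+ it turned to higher without the 3 libraries (2.353e-07) and ran from 0.00632 to 0.985 without single libraries.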

Other observations

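The tests of explanations, the counts over other splits of the libraries and the genes of the next sentences were chosen after the results were seen. Genes of both T cell lineages were seen in Sca-1+ tdT+ libraries. Cd8a was 27.6, 85.9 and 73.6 CPM there and 2.18 and 0 CPM in Sca-1+ tdT- (adjusted p = 0.124), while Trac was 15.5, 35.3 and 25.9 CPM against 1.61 and 1.34 CPM (adjusted p = 0.00994). Trdc, of gamma-delta T cells, was 53.9, 92.9 and 89.9 CPM against 19.9 and 18.1 CPM (adjusted p = 0.238).

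Camera called the T cell list higher in tdT+ libraries of both fractions, with 2 of 24 genes past the test in Sca-1neg, where the library labelled Sca-1neg tdT+ replicate 2 counts as tdT+ and the call was lost with an estimated correlation (adjusted p = 0.066), and 9 of 24 in Sca-1+. In Sca-1+, the cytotoxic effector list summed to at least 411 CPM in tdT+ and at most 122 CPM in tdT- libraries. That fraction holds none of the libraries with liver transcripts, so these cannot be the source there. This follows from the samples and is not the result of a test. Whether they are the source in Sca-1neg stays open, since 1 tdT+ library had under 1% of liver transcripts (58.8 CPM for the list, against at most 18.9 CPM in tdT-). A lower share of keratinocytes in the tdT+ libraries stays open too. The endothelial median in Sca-1+ was -4.94, but it cannot decide this. Sorting by tdT can by itself leave untraced endothelial cells in the tdT- libraries. Keratinocyte lists went both ways in Sca-1+. The basal interfollicular list summed to 30820 to 37010 CPM in tdT+ against 23740 and 26260 CPM in tdT-. The differentiating epidermis list summed to 11890 to 13640 against 10160 and 5359 CPM, so neither was lower. Sums of the bulge and upper follicle lists overlapped, and the hair shaft list was lower (43.9 to 345 against 703 and 713 CPM). T cells among the sorted tdT+ cells may be the source, which stays open. Over all 42 tested genes of the T cell and cytotoxic lists, the log2 ratios between the tdT+ groups had an SD of 1.02. Their median was 11.1-fold. An SD under 1 would favour T cells as the source and over 2 would argue against it. Whether the CD49f+CD34+ gate removed T cells was not tested, and Cd34 was only 22.4 to 35.7 CPM in the Sca-1+ tdT+ libraries. Cd3e reached 117 CPM and Itgae 173 CPM there. Of 24 T cell genes, 3 (Thy1, Tcf7 and Bcl11b) are at 10 CPM or more in Sca-1neg tdT- cells.

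Liver transcripts marked Sca-1neg tdT+ replicate 1, the library labelled Sca-1neg tdT+ replicate 2 and Sca-1neg tdT- replicate 2. Alb was 4393 to 9564 CPM and Apoa1 711 to 1294 CPM in these 3 libraries, and 0 of the 20 liver genes reached 10 CPM in the Sca-1neg tdT- libraries without them. The sorted group is excluded as the source, since Alb reached only 37.3 CPM in the other libraries of the same groups. RNA of an outside source may have entered the 3 libraries, since sorted CD49f+CD34+ cells would not include liver cells. The log2 ratios of the 20 genes between any of them had an SD of at most 0.214. Several liver samples could give a low SD as well, so it does not tell 1 source from several. The predicted gene Gm10800 marked the same libraries, at 12574 to 27175 CPM against 32.3 to 416 CPM in the other 8. A common source does not account for all Xist in the library labelled Sca-1neg tdT+ replicate 2. Its Xist to Alb ratio exceeded those of the other 2 libraries with liver transcripts by at least 2.78 (log2).

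Camera called 11 lists higher and 8 lower of 36 for tdT+ against tdT- in Sca-1neg, 4 and 11 in Sca-1+, 16 and 5 for Sca-1+ against Sca-1neg in tdT-, and 10 and 6 in tdT+. The averaged tdT effect gave 8 and 11 and its difference between fractions 4 and 12. With an estimated correlation the calls were 0, 1, 0, 0, 2 and 0 in this order, and with fry 2, 6, 12, 12, 6 and 1.

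Other splits of the same libraries were fitted in the same way. For tdT+ against tdT- in Sca-1neg, 2 of 10 splits gave as many as the 13 genes, with 1350 in the split that kept the 3 libraries with liver transcripts together, so these samples hold a structure other than the groups. For Sca-1+ against Sca-1neg in tdT+, 1 of 10 splits, the real one, gave 2572 genes and the highest other 0. With 10 splits a share under 0.05 cannot be reached in either comparison. For the averaged tdT effect, 5 of 100 splits gave as many as 457 genes and the highest other 1598. Chance is not excluded there, and all 4 other splits kept the 3 libraries with liver transcripts together.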
